A study of Mus musculus with 8 samples.

How the data were processed

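RNA was measured by sequencing in Merkel cells and in epidermal cells labelled IFE by the submitters, an abbreviation that the labels do not spell out. Both cell types were sorted from the skin of newborn (postnatal day 0) mice that carry a fusion of Atoh1 with green fluorescent protein (GFP). Back skin and paw were dissociated with collagenase and then trypsin and stained for Sca1 (the product of Ly6a) and EpCAM. Merkel cells were taken as GFP-positive, EpCAM-positive and Sca1-negative, and IFE cells as GFP-negative, EpCAM-positive and Sca1-positive. Per the labels, a small fixed amount of RNA was amplified before library construction and sequenced in paired ends. Atoh1, Epcam and Ly6a entered the sort itself, so their values describe the gate and are not independent findings. The labels give 2 skin sites, 2 cell types and 2 libraries for each of the 4 groups, 8 libraries in all, and every library was used. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

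The authors deposited 2 kinds of values per library. The first are deposited gene counts, whole numbers over 24538 gene rows. The second are deposited FPKM values, fragment counts that the authors had already scaled to transcript length and library depth. Per the submitters' processing notes the reads were placed on the mm10 genome, and TopHat2 2.0.13, Cufflinks 2.2.1, featureCounts from Subread 1.4.6 and DESeq2 1.6.3 were used. The notes do not give the gene annotation, the strand setting or the design of their test. No mitochondrially encoded gene is among the rows of the count files. Chromosome positions are from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10. All 153 genes looked up by symbol were found there, and 6 of them shared more than 20% of their exonic bases with another gene.

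The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 15151 genes, and library sizes were scaled by TMM. The model had 1 mean per group over all 8 libraries, which leaves 4 residual degrees of freedom. Each comparison was tested with the edgeR quasi-likelihood F test (glmQLFit and glmQLFTest), and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. The 5 comparisons were paw Merkel against paw IFE, back Merkel against back IFE, paw Merkel against back Merkel, paw IFE against back IFE, and the difference between the first and the second of these, tested as an interaction. Levels are given as CPM (counts scaled to a common library size) after TMM scaling, as mean ± SD over the 2 libraries of a group, and fold changes as log2 with their standard error (SE) from the model. Where all libraries of the lower group were at 0, the fold is a lower bound computed against a floor of 3 counts over the group. Such floors cover counting error only, because amplified reads are not independent molecules.

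A set of 27 gene lists was fixed. These lists cover Merkel cell identity, vesicle release and secretory granules, voltage-gated channels, neuropeptides and neurotrophic factors, basal keratinocyte genes, terminal differentiation of keratinocytes, hair follicle, palmoplantar and stress keratins, the Sonic hedgehog, FGF, BMP, EDA and NF-kappaB, WNT and Notch pathways, Hox genes, limb patterning, polycomb, cell cycle, early response and heat shock, mitochondrially encoded genes, and markers of melanocytes, fibroblasts, endothelium, immune and Langerhans cells, Schwann and peripheral glia, skeletal muscle and erythroid cells. The 25 lists with at least 3 measured members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and the p-values were adjusted by Benjamini-Hochberg over these lists. The test was repeated with an estimated correlation, and fry was run beside it. Members past the threshold were counted after adjustment over all genes and again adjusted over the list alone. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median.

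The genes named in each comparison follow a fixed rule. A panel of 18 genes is considered in every comparison (Atoh1, Epcam, Ly6a, Sox2, Isl1, Krt8, Krt18, Krt20, Piezo2, Krt5, Krt14, Krt10, Shh, Gli1, Ptch1, Fgfr2, Edar and Bmp4). To these are added the 8 genes with the largest fold change in each direction among those past the threshold, without overlap between the groups and with a mean of at least 10 CPM in the higher group, and up to 4 members of each list with the smallest adjusted p plus up to 1 member going the other way. Predicted genes, pseudogenes and genes without a symbol were left out of the ranking. The groups, comparisons, tests, lists, naming rule and alternatives described here were fixed before the data were examined, except the thinned libraries named in the last paragraph.

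Total counts per library ran from 11139306 to 26195076. The tests were tried on simulated data with 200 changed genes per comparison and 1 spread per gene, estimated over all groups. The real groups differed in spread, with a median absolute log2 difference between replicates of 1.00 in paw Merkel and 0.51 in paw IFE cells. Recovery and false calls in comparisons with paw Merkel cells may therefore differ from the simulated ones. The changed genes were drawn from those with a mean of at least 10 CPM, so recovery of less abundant genes was not measured. In the 4 direct comparisons the edgeR test recovered 22.4% to 29.9% of genes changed 4-fold, 76.1% to 85.1% of those changed 16-fold and 92.4% to 98.5% of those changed 64-fold, with 4 to 11 false calls. For the interaction it recovered 5.97%, 70.1% and 84.8%, with 10 false calls. DESeq2 1.42.0 made 86 to 129 false calls among 242 to 296 calls in the direct comparisons.

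Alternatives changed 1 named choice, and some moved others with it. Those on FPKM changed the values, the test and the filter together, DESeq2 brought its own scaling, and the lists under DESeq2 and limma-trend were tested by ranks in place of camera. The filter on low counts was applied again where libraries or groups were left out or libraries thinned, so the genes tested differed (13975 with only the groups compared, 14619 when thinned and 16163 to 16425 without a library). They were DESeq2 and limma-trend in place of edgeR, RLE and upper-quartile scaling, no filter on low counts, a filter of at least 5 CPM in 2 libraries, a fit of only the groups compared, a block for the replicate number, leaving out each of the 8 libraries in turn, limma on log2(FPKM + 1) or log2(FPKM + 0.1) of genes at 1 FPKM or more in 2 libraries, log2(FPKM + 1) without a filter, a 2-fold minimum, an adjusted p under 0.01, and the estimated inter-gene correlation. Random thinning of every library to the total of the smallest was added after seeing the data. Where a library was left out, the lone library of its group was assumed to vary like those of the other groups. Replicate numbers recur across groups, but the correlations of the residuals between libraries of the same number lay between -0.04 and 0.08 over the 6 pairs of groups, so libraries were not paired in the main comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.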

Results

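RNA was measured in 8 libraries of sorted mouse skin cells, 2 from each of 4 groups: paw Merkel cells, paw IFE cells, back Merkel cells and back IFE cells. Merkel cells are epidermal touch receptors, and the IFE cells are EpCAM-positive, Sca1-positive epidermal cells of the same skin. The title of the study concerns hairy and glabrous skin, and the labels place the cells in back skin and paw. Total counts were 19300202 and 12292015 in paw Merkel libraries 1 and 2, and 23197142 and 20016954 in paw IFE libraries 1 and 2. They were 13049816 and 11139306 in back Merkel libraries 1 and 2, and 17510481 and 26195076 in back IFE libraries 1 and 2. Paw Merkel cells had counts in 14926 ± 812 genes (mean ± SD over the 2 libraries of the group, as for every ± given here). Paw IFE cells had counts in 15692 ± 251 genes, back Merkel cells in 14458 ± 645 and back IFE cells in 15188 ± 665. Adjusted p-values for genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 15151 genes. For each gene given with a fold change past the threshold, both libraries of the higher group lay above both of the lower one, except Hoxc10 in back skin.

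Merkel cells lay apart from IFE cells along the first principal component, which held 51.8% of the variance of the log2 CPM values. Paw Merkel cells were the least alike of the replicate pairs: their median absolute log2 difference was 1.00, against 0.51 in paw IFE, 0.74 in back Merkel and 0.62 in back IFE cells. Pearson correlations of log2 CPM between the libraries of a group were 0.826 in paw Merkel, 0.923 in paw IFE, 0.872 in back Merkel and 0.897 in back IFE cells. Back IFE library 2 correlated more closely with paw IFE libraries 1 and 2 (0.931 and 0.918) than with back IFE library 1 (0.897). Over 26 Hox genes, which carry position along the body, its correlations with paw IFE libraries 1 and 2 were 0.728 and 0.87, against -0.124 with back IFE library 1. These are correlations across genes, which are not independent replicates. Paw Merkel library 1 stood closer to the IFE libraries on the first component (-55.2) than paw Merkel library 2 (-152). On the second component paw Merkel library 2 stood apart from every other library (-164, against -13.5 to 93.9).

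**Figure D1:**
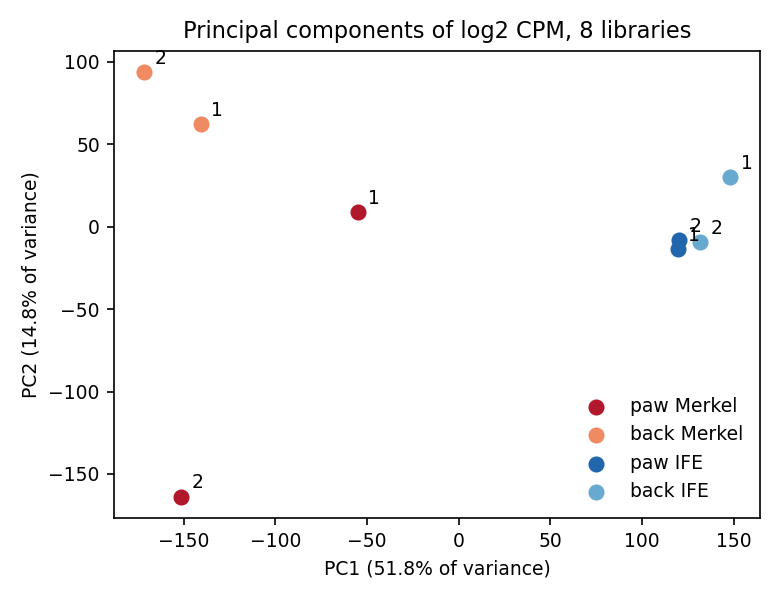
Position of the 8 libraries on the first principal component (horizontal axis, 51.8% of variance) and the second (vertical axis, 14.8% of variance) of log2 CPM; each point is 1 library, coloured by group. Paw Merkel library 1 lies at -55.2 on the first component, between the other Merkel libraries and the IFE libraries, and paw Merkel library 2 at -164 on the second.

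The comparison of Merkel with IFE cells of the paw asks which genes set the touch receptor apart from the epidermis around it. Paw Merkel cells carried the transcripts of the known Merkel programme at levels far above those of IFE cells. Atoh1, the transcription factor that specifies Merkel cells and whose fusion was used in the sort (chromosome 6, 64729125 to 64731245, GRCm38), measured 294 ± 14.5 CPM against 0.115 ± 0.0471 CPM (log2 fold change 11.27, SE 0.64, adjusted p = 3.19e-06). Krt20, a keratin of Merkel cells (chromosome 11, 99428403 to 99438150), measured 408 ± 67.3 CPM against 0.315 ± 0.0426 CPM (log2 fold change 10.31, SE 0.47, adjusted p = 8.41e-07). Piezo2, the mechanically gated channel of touch (chromosome 18, 63010213 to 63387183), measured 866 ± 482 CPM against 11.9 ± 1.55 CPM (log2 fold change 6.19, SE 0.47, adjusted p = 2.08e-05), and without paw Merkel library 2 its log2 fold change was 5.47. Isl1 and Sox2, transcription factors of the Merkel lineage, had log2 fold changes of 9.96 and 9.56, the latter 8.96 without paw Merkel library 1 and 10.31 without paw IFE library 1.

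Some genes of transmitter release and excitability were higher in paw Merkel cells too, among them 22 of 38 vesicle release genes and 10 of 31 voltage-gated channels. Myt1, a neuronal transcription factor, measured 471 ± 49.8 CPM against 0.266 CPM (log2 fold change 10.75, SE 0.47, adjusted p = 8.41e-07). Syt13 and Sv2c, proteins of secretory vesicles, had log2 fold changes of 7.06 and 9.51. Cacna1a, a presynaptic calcium channel, measured 204 ± 125 CPM against 2.57 CPM (log2 fold change 6.31, SE 0.55, adjusted p = 4.74e-05), and 5.50 on the same log2 scale without paw Merkel library 2. The peptide hormone gene Cck had a log2 fold change of 6.92 (adjusted p = 0.00165), while the neuropeptide list did not pass its test (camera adjusted p = 0.0833). Cntnap2, a neuronal adhesion protein, measured 28.4 ± 1.91 CPM against 0 counts in paw IFE cells, at least 430-fold higher against a floor of 3 counts over the group.

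Of 27 basal keratinocyte genes 15 were lower in paw Merkel cells, though the list did not pass with an estimated correlation (adjusted p = 0.0676). Some receptor genes were lower too, although the FGF and Notch lists passed no threshold. Krt5, a basal keratin (chromosome 15, 101707070 to 101712898), measured 967 ± 553 CPM against 15204 ± 1856 CPM (log2 fold change -3.97, SE 0.50, adjusted p = 0.000668), and -4.74 without paw Merkel library 1. Fgfr2, the receptor of epidermal fibroblast growth factors, measured 469 ± 126 CPM against 2172 ± 233 CPM (log2 fold change -2.21, SE 0.37, adjusted p = 0.00432). Fgfr3 and Notch1, further receptors, had log2 fold changes of -3.10 and -3.17. Gas1, a hedgehog co-receptor, measured 20.3 ± 4.75 CPM against 185 ± 54.3 CPM (log2 fold change -3.18, SE 0.50, adjusted p = 0.00289). Bub1, a mitotic checkpoint kinase, measured 9.76 ± 2.46 CPM against 90.9 ± 3.1 CPM (log2 fold change -3.21, SE 0.48, adjusted p = 0.00205). Col5a1, a fibrillar collagen, measured 6.33 ± 2.04 CPM against 144 ± 48.6 CPM (log2 fold change -4.50, SE 0.69, adjusted p = 0.00275). Atp12a, a proton pump, had 0 counts in paw Merkel cells against 14.1 CPM and was at least 146-fold lower (adjusted p = 0.0172). This call was lost without paw IFE library 2 (adjusted p = 0.0858).

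By the edgeR test 649 genes were higher and 292 lower in paw Merkel cells, 941 of 15151, and 3201 had an unadjusted p under 0.05. DESeq2 called 2227 genes and limma-trend 1096. The count rose to 2369 without paw Merkel library 1, which kept 901 of the 941, and fell to 620 without paw IFE library 1 and 561 without paw IFE library 2. Of the 18 panel genes 7 were higher, 3 lower and 8 past no threshold. Of the 70 genes of the naming rule past the threshold, 45 stayed past it without any 1 library. Of the others, 20 were lost without paw IFE library 2, 15 without paw Merkel library 2, 13 without paw IFE library 1, 3 without paw Merkel library 1, 2 each without back Merkel library 1 and back IFE library 1, and 1 without back Merkel library 2 (adjusted p up to 0.566). Neither Epcam (321 against 196 CPM, log2 fold change 0.71, adjusted p = 0.181) nor Ly6a (0.911 against 20.7 CPM, log2 fold change -4.42, adjusted p = 0.0917), both used in the sort, passed the threshold.

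Among the gene lists, Merkel identity genes moved furthest: 23 of 29 were higher and 0 lower in paw Merkel cells (26 higher adjusted over the list alone), with a median log2 fold change of 8.20 (8.03 with genes at their bound) and an adjusted p of 1.77e-30 by camera (adjusted p = 0.0111 with an estimated correlation). Vesicle release genes followed with 22 of 38 higher (25 adjusted over the list alone, median 4.86, camera adjusted p = 2.86e-16, adjusted p = 0.0316 with an estimated correlation). Voltage-gated channels had 10 of 31 higher (13 adjusted over the list alone, median 3.56, or 3.43 with genes at their bound, camera adjusted p = 6.05e-10, adjusted p = 0.0229 with an estimated correlation). Basal keratinocyte genes had 15 of 27 lower (23 adjusted over the list alone, median -1.84, camera adjusted p = 8.45e-11, adjusted p = 0.0676 with an estimated correlation). Cell cycle genes had 10 of 36 lower (26 adjusted over the list alone, median -1.99, camera adjusted p = 2.22e-10, adjusted p = 0.123 with an estimated correlation). Immune markers had 5 of 18 lower (10 adjusted over the list alone, median -4.63, or -4.22 with genes at their bound, camera adjusted p = 4.34e-05, adjusted p = 0.282 with an estimated correlation). Fibroblast markers had 3 of 12 lower (7 adjusted over the list alone, median -2.52, camera adjusted p = 0.000783, adjusted p = 0.187 with an estimated correlation), and without paw Merkel library 1 the camera value was 0.0699. Terminal differentiation genes had 1 higher and 2 lower of 35 by either adjustment (median -1.09, camera adjusted p = 0.00878, adjusted p = 0.749 with an estimated correlation), and the camera value was 0.984 without paw Merkel library 2 and 0.169 without paw IFE library 2.

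The remaining lists did not pass the camera test in the paw. Their adjusted p-values were 0.0532 for Hox genes (0 called), 0.0532 for melanocyte markers (Kit alone, higher) and 0.0833 for neuropeptides (3 higher and 1 lower of 12, median 2.96). They were 0.0902 for WNT (2 higher and 2 lower of 34), 0.156 for Sonic hedgehog (1 lower of 16), 0.266 for EDA and NF-kappaB (0 called) and 0.4 for endothelium. They were 0.413 for Notch (2 higher and 3 lower of 19), 0.413 for polycomb (1 higher of 29) and 0.929 for early response and heat shock (1 higher and 1 lower of 25). Palmoplantar keratins, limb patterning, Schwann cell and muscle markers stood at 0.837, and hair follicle (1 lower of 24), FGF (2 lower of 25) and BMP genes (1 lower of 28) at 0.986. Adjusted over the list alone, 6 neuropeptide genes were higher and 2 lower, with 2 higher and 6 lower for WNT, 2 and 4 for Notch, 2 and 2 for hair follicle, and 1 and 3 for both Sonic hedgehog and EDA. The counts were 1 higher and 2 lower for FGF and early response genes and 0 higher and 1 lower for endothelium, and in the remaining lists they were those over all genes. The sign of the median, the mean and the test differed in some of these lists, though not in those past the threshold. The hair follicle list had a median of 0.17 and the palmoplantar list a median of 0.73 with the test pointing down. FGF genes had a median of -0.23 and a mean of 0.47, BMP genes a median of 0.08 and a mean of -0.20, and limb genes a median of -0.66 and a mean of 0.08. The only measured erythroid marker had a log2 fold change of -0.32 and was not tested as a list, and 0 mitochondrially encoded genes were measured.

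The same question in back skin gave a larger set of differences. Krt20 measured 913 ± 97.3 CPM in back Merkel cells against 0.462 CPM in back IFE cells (log2 fold change 10.95, SE 0.48, adjusted p = 4.9e-07). Piezo2 measured 1283 ± 24.5 CPM against 7.0 CPM (log2 fold change 7.52, SE 0.50, adjusted p = 7.32e-06). Isl1 (chromosome 13, 116298281 to 116309689) measured 572 ± 9.31 CPM against 0.37 CPM (log2 fold change 10.59, SE 0.53, adjusted p = 9.2e-07). Atoh1 measured 196 ± 25.2 CPM against 0.31 CPM (log2 fold change 9.21, SE 0.58, adjusted p = 5.19e-06), and 10.16 on the log2 scale without back IFE library 2. Sox2 (chromosome 3, 34650405 to 34652461) had a log2 fold change of 10.32 (adjusted p = 1.81e-05), and 10.94 without back IFE library 2. Insm1, a transcription factor of neuroendocrine cells, measured 637 ± 109 CPM against 0.362 CPM (log2 fold change 10.76, SE 0.59, adjusted p = 2.18e-06). Prmt8, a brain-enriched methyltransferase, measured 151 ± 42.7 CPM against 0 counts and was at least 2192-fold higher. Slc17a6, which loads glutamate into vesicles, measured 52.7 ± 14.9 CPM against 0 counts and was at least 764-fold higher.

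Of 27 basal genes 21 were lower and 1 higher in back Merkel cells, and of 36 cell cycle genes 29 were lower, though neither list passed with an estimated correlation (adjusted p = 0.0659 for both). Fgfr2 and Gli3 were lower too, although the FGF, Notch and Sonic hedgehog lists passed no threshold. Krt14, the partner keratin of Krt5 (chromosome 11, 100203162 to 100207548), measured 137 ± 42.6 CPM against 5207 ± 1171 CPM (log2 fold change -5.25, SE 0.48, adjusted p = 5.32e-05). Trp63, the transcription factor of the basal layer, measured 165 ± 23.3 CPM against 2067 ± 0.164 CPM (log2 fold change -3.65, SE 0.35, adjusted p = 7.32e-05). Fgfr2 measured 174 ± 63.3 CPM against 2599.6 ± 401 CPM (log2 fold change -3.90, SE 0.39, adjusted p = 9.18e-05). Gli3, a transcription factor of hedgehog signalling, measured 0.521 CPM against 88.1 ± 11.8 CPM (log2 fold change -7.39, SE 0.81, adjusted p = 0.000172). Ccna2, a cyclin of S phase and mitosis (chromosome 3, 36564865 to 36572150), measured 1.9 ± 0.332 CPM against 185 ± 24.2 CPM (log2 fold change -6.60, SE 0.59, adjusted p = 4.32e-05). Mki67, a proliferation marker, measured 125 ± 41.3 CPM against 2276 ± 810 CPM (log2 fold change -4.19, SE 0.40, adjusted p = 7.39e-05). Id2, a target of bone morphogenetic protein signalling (chromosome 12, 25093799 to 25097140), had 0 counts against 11.2 CPM and was at least 90.5-fold lower (adjusted p = 0.00314). Cd74, an antigen presentation gene, measured 0.0869 CPM against 271 ± 299 CPM at low counts, with 483 and 59.6 CPM in back IFE libraries 1 and 2.

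**Figure D2:**
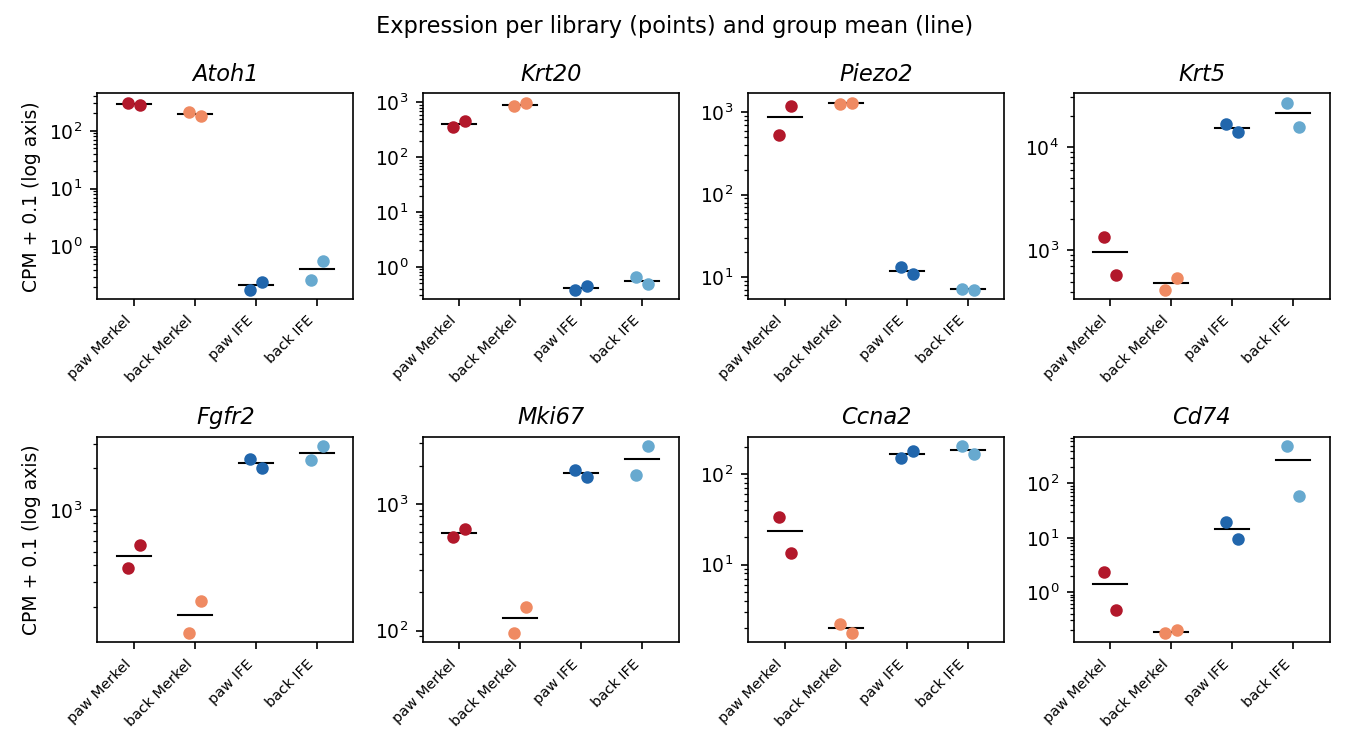
CPM plus 0.1 (vertical log axis) of Atoh1, Krt20, Piezo2, Krt5, Fgfr2, Mki67, Ccna2 and Cd74 in the 4 groups; each point is 1 library and each line the mean of a group. Krt20 stands at 408 and 913 CPM in paw and back Merkel cells, and Ccna2 at 23.5 CPM in paw Merkel cells against 1.9 CPM in back Merkel cells.

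In back skin the edgeR test called 1210 genes higher and 1128 lower in Merkel cells, 2338 in all, with 4627 at an unadjusted p under 0.05. DESeq2 called 3963 and limma-trend 3195. The count fell to 1307 without back Merkel library 2 and 1555 without back IFE library 1. Of the panel 7 genes were higher, 4 lower and 7 past no threshold. Of the 98 genes of the naming rule past the threshold, 65 stayed past it without any 1 library. Of the others, 27 were lost without back Merkel library 1, 26 without back Merkel library 2, 19 without back IFE library 2, 18 without back IFE library 1, 6 without paw IFE library 2 and 4 without paw IFE library 1 (adjusted p up to 0.766). Ly6a, used in the sort, was lower (1.09 against 47.4 CPM, log2 fold change -5.46, adjusted p = 0.0286), a call lost without back Merkel library 1 (adjusted p = 0.11) and back IFE library 2 (adjusted p = 0.0634). Epcam did not differ past the threshold (267 against 347 CPM, log2 fold change -0.38, adjusted p = 0.404). Ptch1, the hedgehog receptor, had a log2 fold change of -0.92 (adjusted p = 0.281), -1.63 without back IFE library 2 (adjusted p = 0.0203) and 0.48 without back IFE library 1. Back IFE library 2, which resembled paw IFE cells in its Hox genes, entered every value of this comparison, and without it 1786 genes were called. The log2 fold change of -8.82 of Hoxc10 rested on back IFE library 2 (83.9 CPM, against 0 in library 1) and was 3.65 without it (adjusted p = 0.366).

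Merkel identity genes were again the furthest apart in back skin, with 25 of 29 higher (27 adjusted over the list alone, median log2 fold change 9.69, or 9.10 with genes at their bound, camera adjusted p = 6.94e-26, adjusted p = 0.0152 with an estimated correlation). Vesicle release genes had 26 of 38 higher (29 adjusted over the list alone, median 6.23, camera adjusted p = 1.16e-16, adjusted p = 0.0302 with an estimated correlation) and channels 14 of 31 (20 adjusted over the list alone, median 5.71, or 5.49 with genes at their bound, camera adjusted p = 2.81e-10, adjusted p = 0.021 with an estimated correlation). Cell cycle genes had 29 of 36 lower (32 adjusted over the list alone, median -4.00, camera adjusted p = 1.3e-16, adjusted p = 0.0659 with an estimated correlation). Basal genes had 1 higher and 21 lower of 27 (2 and 23 adjusted over the list alone, median -2.95, camera adjusted p = 6.74e-10, adjusted p = 0.0659 with an estimated correlation). Immune markers had 7 of 18 lower (16 adjusted over the list alone, median -8.34, or -5.29 with genes at their bound, camera adjusted p = 2.59e-09, adjusted p = 0.167 with an estimated correlation). Fibroblast markers had 1 higher and 8 lower of 12 (1 and 9 adjusted over the list alone, median -4.78, or -4.72 with genes at their bound, camera adjusted p = 0.000543, adjusted p = 0.167 with an estimated correlation). WNT genes had 2 higher and 11 lower of 34 (2 and 14 adjusted over the list alone, median -1.93, camera adjusted p = 0.0161, adjusted p = 0.237 with an estimated correlation), and the camera value was 0.142 without back IFE library 2. Terminal differentiation genes had 1 lower of 35 and 0 adjusted over the list alone (median -1.48, camera adjusted p = 0.0475, adjusted p = 0.69 with an estimated correlation). The camera value of that list was 0.109 without back Merkel library 1, 0.0773 without back Merkel library 2 and 0.172 without back IFE library 1.

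Other back skin lists stayed above the threshold of camera. Hair follicle genes (1 higher and 4 lower of 24) and BMP genes (1 higher and 6 lower of 28) had an adjusted p of 0.0544. The value was 0.0572 for palmoplantar keratins (3 lower of 9), 0.0813 for Sonic hedgehog (5 lower of 16), and 0.138 for early response and heat shock (4 lower of 25). It was 0.226 for neuropeptides (4 higher and 1 lower of 12), 0.231 for melanocyte markers (1 higher of 7) and 0.285 for limb patterning (3 lower of 13). Further values were 0.374 for Hox genes (3 lower of 28), 0.471 for Schwann cells, 0.485 for EDA and NF-kappaB (3 lower of 16), 0.526 for muscle and 0.665 for endothelium. The highest values were 0.83 for Notch (3 higher and 3 lower of 19) and polycomb (2 higher and 3 lower of 29), and 0.952 for FGF (2 higher and 3 lower of 25). Adjusted over the list alone, hair follicle genes had 1 higher and 6 lower, palmoplantar keratins 4 lower, Sonic hedgehog genes 6 lower, early response genes 8 lower, limb genes 4 lower and Hox genes 2 lower. Neuropeptides had 4 higher and 2 lower, EDA genes 1 and 4, Notch genes 5 and 5, and polycomb and FGF genes 3 and 3, and in the remaining lists the counts were those over all genes. No list past the threshold differed in the sign of its median, mean and test. The Notch list had a median of -1.08 and a mean of 1.05, the FGF list a median of -0.25 and a mean of 0.12, and the polycomb list a median of -0.16 with the test pointing up.

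Most genes called between Merkel and IFE cells in the paw were also called in back skin, while 1524 of the 2338 called in back skin were called there alone. Of the 649 genes higher in paw Merkel cells, 573 (88.3%) were also higher in back Merkel cells, where 51.8 would be shared by chance, and of the 292 lower ones 241 (82.5%) were also lower, against 21.7 by chance. No gene was called in opposite directions (0). Of the 2465 genes called at either site, 2342 (95.0%) had fold changes of the same sign. The count of genes lower at both sites was 645 without paw Merkel library 1, 151 without paw Merkel library 2, 149 without paw IFE library 1 and 139 without paw IFE library 2. Among the 1524 genes called in back skin alone, 1408 had the same sign in the paw, so a call at 1 site alone shows no difference between sites.

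**Figure D3:**
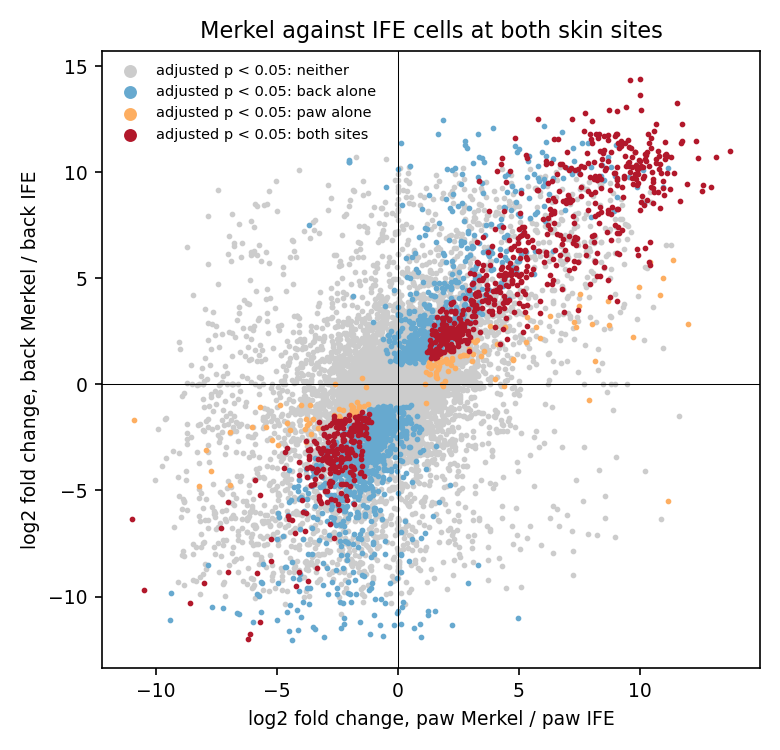
Log2 fold change of Merkel over IFE cells in the paw (horizontal axis) and in back skin (vertical axis); each point is 1 gene, coloured by the comparisons in which it passed the threshold. Genes past the threshold at both sites, 573 higher and 241 lower, lie in the quadrants of equal sign.

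Merkel cells of the paw were then set against those of back skin, which asks whether the touch receptors of the 2 sites differ. Of the genes higher in paw Merkel cells, Ccna2 and Cenpf act in cell division, Id2 and Id3 respond to bone morphogenetic proteins, and Gli3 acts in hedgehog signalling. In back skin Ccna2 and Gli3 were far lower in Merkel than in IFE cells. IFE RNA carried over into the paw Merkel libraries could therefore raise these genes, which was not tested for single genes. Ccna2 measured 23.5 ± 14.4 CPM against 1.9 ± 0.332 CPM (log2 fold change 3.62, SE 0.52, adjusted p = 0.0336), and 2.80 on the log2 scale without paw Merkel library 1. Cenpf, a kinetochore protein of mitosis (chromosome 1, 189640606 to 189688086), measured 291 ± 60.8 CPM against 43.6 ± 17.8 CPM (log2 fold change 2.74, SE 0.40, adjusted p = 0.0336). Id2 measured 24.3 ± 10.5 CPM against 0 counts in back Merkel cells and was at least 207-fold higher (adjusted p = 0.0429). Its relative Id3 (chromosome 4, 136143497 to 136145755) measured 93.3 ± 11.5 CPM against 4.56 ± 2.16 CPM (log2 fold change 4.35, SE 0.70, adjusted p = 0.0429), and 4.98 on the log2 scale without back Merkel library 1. Gli3 (chromosome 13, 15463235 to 15730026) measured 22.1 ± 18 CPM against 0.521 CPM (log2 fold change 5.41, SE 0.76, adjusted p = 0.0336), 4.17 without paw Merkel library 1 and 6.06 without paw Merkel library 2. Sox2ot, the noncoding transcript that overlaps Sox2 (chromosome 3, 34104270 to 34682619), was the single lower gene at 101 ± 12.4 CPM against 509 ± 42.8 CPM (log2 fold change -2.33, SE 0.34, adjusted p = 0.0336). The 15 called genes of the naming rule, these 6 among them, all lost the call without back Merkel library 1 (adjusted p from 0.0928 to 0.142) and without back Merkel library 2 (adjusted p from 0.0934 to 0.201).

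The edgeR test called 27 genes higher and 1 lower in paw Merkel cells, with 1550 at an unadjusted p under 0.05, while DESeq2 called 512 and limma-trend 19. The count was 177 without paw Merkel library 1, 119 without paw Merkel library 2, 58 without paw IFE library 1 and 46 without paw IFE library 2. It was 1 without back Merkel library 1, 1 without back Merkel library 2, 103 without back IFE library 1 and 78 without back IFE library 2. A fit of the compared groups alone called 5 genes, 0 of them among the 28. The smallest adjusted p belonged to Antxr1, an anthrax toxin receptor that binds collagen (log2 fold change 3.91, adjusted p = 0.0156), a gene chosen after its values were seen. Of the 18 panel genes 0 passed the threshold. The smallest adjusted p among them was 0.178 for Fgfr2 (log2 fold change 1.43). Krt20 (-1.16), Piezo2 (-0.57), Isl1 (-0.73) and Sox2 (-0.75) were also past no threshold.

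In the lists of this comparison, 8 lay higher and 3 lower in paw Merkel cells by camera, and 0 of them passed with an estimated correlation (smallest adjusted p = 0.288). Cell cycle genes led with 5 of 36 higher (20 adjusted over the list alone, median 1.57, camera adjusted p = 3.55e-12, adjusted p = 0.288 with an estimated correlation). BMP genes had 2 of 28 higher (4 adjusted over the list alone, median 0.83, camera adjusted p = 0.00351) and fibroblast markers 2 of 12 (5 higher and 1 lower adjusted over the list alone, median 1.70, or 2.94 with genes at their bound, camera adjusted p = 0.0316). Hair follicle genes (median 1.29, camera adjusted p = 0.0273), WNT genes (median 0.88, 0.0274) and palmoplantar keratins (median 1.80, 0.0489) were higher as lists with 0 members past the threshold and 1 each adjusted over the list alone. Basal genes were higher as a list (median 0.77, camera adjusted p = 0.0274) with 0 called and 12 higher and 2 lower adjusted over the list alone. Early response genes were too (median 0.55, 0.0489), with 0 by either adjustment. Vesicle release genes (median -0.84, camera adjusted p = 0.00351), channels (median -0.68, 0.0274) and identity genes (median -0.45, 0.0436, 3 lower adjusted over the list alone) were lower as lists with 0 members past the threshold over all genes. Hox genes had 0 called over all genes and 4 higher and 6 lower of 28 adjusted over the list alone (median 0.05, mean -0.78, camera adjusted p = 0.0753). Sonic hedgehog genes had 1 of 16 higher and 4 adjusted over the list alone (camera adjusted p = 0.2), and FGF and limb genes 0 called and 3 each adjusted over the list alone (0.534 and 0.2). Terminal differentiation genes had a median of 0.34 while the test pointed down (camera adjusted p = 0.539), and the signs of median, mean or test also differed for neuropeptide, Notch, melanocyte and endothelial genes, past no threshold. Without paw Merkel library 1 the camera adjusted p was 0.3 for hair follicle, 0.13 for BMP, 0.39 for basal and palmoplantar and 0.23 for WNT genes. It was 0.203 for fibroblast, 0.693 for early response, 0.365 for vesicle, 0.514 for channel and 0.446 for identity genes, and of the 11 lists cell cycle genes alone stayed past the threshold. Without back Merkel library 1 the call was lost by 8 of the 11 lists (adjusted p from 0.0587 to 0.268), and without back Merkel library 2 by 5 (up to 0.384). Without paw Merkel library 2 it was lost by identity (0.117), hair follicle (0.117) and fibroblast genes (0.0779). Identity genes also lost it without paw IFE library 1 (0.184), paw IFE library 2 (0.205), back IFE library 1 (0.0691) and back IFE library 2 (0.0679). Early response genes without back IFE library 1 (0.0601) and back IFE library 2 (0.0585) lost it too, as did hair follicle genes without paw IFE library 1 (0.0569).

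IFE cells of the paw and of back skin did not differ in any single gene past the threshold. Krt5 measured 15204 ± 1856 CPM in paw IFE cells against 21141 ± 7725 CPM in back IFE cells (log2 fold change -0.48, adjusted p = 1). Krt14 (log2 fold change -0.80), Fgfr2 (-0.26) and the suprabasal keratin Krt10 (0.53) also had an adjusted p of 1. Back IFE libraries 1 and 2 did not share their positional genes. Hoxc10 measured 0 and 83.9 CPM in them, against 62.3 and 73.4 CPM in paw IFE libraries 1 and 2, and Hoxb3 48.6 and 3.21 CPM, against 6.44 and 2.47 CPM. Immune markers were the single list past the camera threshold, though not with an estimated correlation (adjusted p = 0.848). Ptprc, a surface protein of white blood cells, measured 2.28 and 1.38 CPM in paw IFE libraries 1 and 2 and 53.6 and 21.9 CPM in back IFE libraries 1 and 2. Csf1r, the receptor of macrophage growth factors, measured 9.57 and 8.93 CPM against 66.6 and 24.8 CPM. The edgeR test called 0 genes here, with 643 at an unadjusted p under 0.05 and a smallest adjusted p of 0.464, while DESeq2 called 84 and limma-trend 0. The count was 14 without paw IFE library 1 and 67 without back IFE library 2, the library that resembled paw IFE cells in its Hox genes. The immune list had 0 members past the threshold over all genes and 5 lower adjusted over the list alone (median log2 fold change -3.01, camera adjusted p = 1.34e-10), and the next list, Notch, stood at 0.0515. Signs of median, mean or test differed for identity, neuropeptide, hair follicle, Sonic hedgehog, limb and early response genes, past no threshold. With 0 genes called between the IFE sites, no gene could be called in both cell types, so the shared count of 0 carries no result. By DESeq2, which called 84 genes between the IFE sites, 6 had the same skin site difference in Merkel cells. In the simulated data DESeq2 made 101 false calls in the comparison of IFE sites, so these calls carry little weight. The site differences of the cell types correlated at 0.03 across genes, which are not independent replicates. That value includes back IFE library 2.

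The interaction asks whether the difference between Merkel and IFE cells was itself different between paw and back skin. Krt20, Piezo2, Krt5 and the other panel genes gave no call (0 of 18, smallest adjusted p = 0.371). Over all genes the edgeR test called 0, with 1365 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0600 for Antxr1. DESeq2 called 273 genes and limma-trend 0. The count was 3 without paw Merkel library 1, 27 without paw Merkel library 2, 9 without paw IFE library 1, 25 without back IFE library 1 and 41 without back IFE library 2. As lists, cell cycle genes were less depleted in Merkel cells of the paw than of back skin (median log2 difference 1.80, 0 called and 14 higher adjusted over the list alone, camera adjusted p = 3.26e-11, adjusted p = 0.325 with an estimated correlation). Immune markers also had a positive interaction (median 2.86, 0 called and 1 higher adjusted over the list alone, camera adjusted p = 8.6e-06, adjusted p = 0.33 with an estimated correlation). Their summed level was low in paw Merkel (19.1 and 2.30 CPM) and back Merkel libraries (5.86 and 8.21 CPM), and the Merkel sites did not differ past the threshold (camera adjusted p = 0.569). In IFE cells it was 163 and 171 CPM in the paw and 1374 and 343 CPM in back skin, so this interaction followed the IFE cells. Vesicle release (median -1.11, camera adjusted p = 0.00463), channel (-0.55, 0.0154) and identity genes (-1.04, 0.0339) were less enriched in the paw by camera, though not with an estimated correlation (adjusted p = 0.33, 0.325 and 0.33). Basal (0.90, 0.0339), hair follicle (2.00, 0.0339) and BMP genes (1.00, 0.0391) stood higher by camera, though not with an estimated correlation (adjusted p = 0.411, 0.33 and 0.517). In these 6 lists 0 members were called over all genes. Adjusted over the list alone, 1 vesicle gene and 1 channel gene were lower, and 5 basal and 2 BMP genes higher. The medians of terminal differentiation (0.64) and Hox genes (1.11) were positive while the test pointed down, and signs also differed for neuropeptide, FGF, EDA, endothelial and Schwann cell genes, past no threshold.

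Leaving out a library ended some of the interaction calls on lists, though not those of cell cycle and immune genes. Without paw Merkel library 1 or without back Merkel library 1 the other 6 lists lost the call (adjusted p from 0.225 to 0.531 and from 0.0506 to 0.215). Without paw Merkel library 2, identity (0.114), hair follicle (0.128) and BMP genes (0.0527) lost it. Without paw IFE library 1, channel (0.139), hair follicle (0.383) and BMP genes (0.164) lost it. Without paw IFE library 2 the call was lost by identity (0.479), channel (0.0768), basal (0.0768) and hair follicle genes (0.166). Without back Merkel library 2, identity (0.156), channel (0.132), hair follicle (0.59) and BMP genes (0.116) lost the call. Without back IFE library 2 it was lost by identity (0.192), channel (0.248), basal (0.0548), hair follicle (0.328) and BMP genes (0.248).

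**Figure D4:**
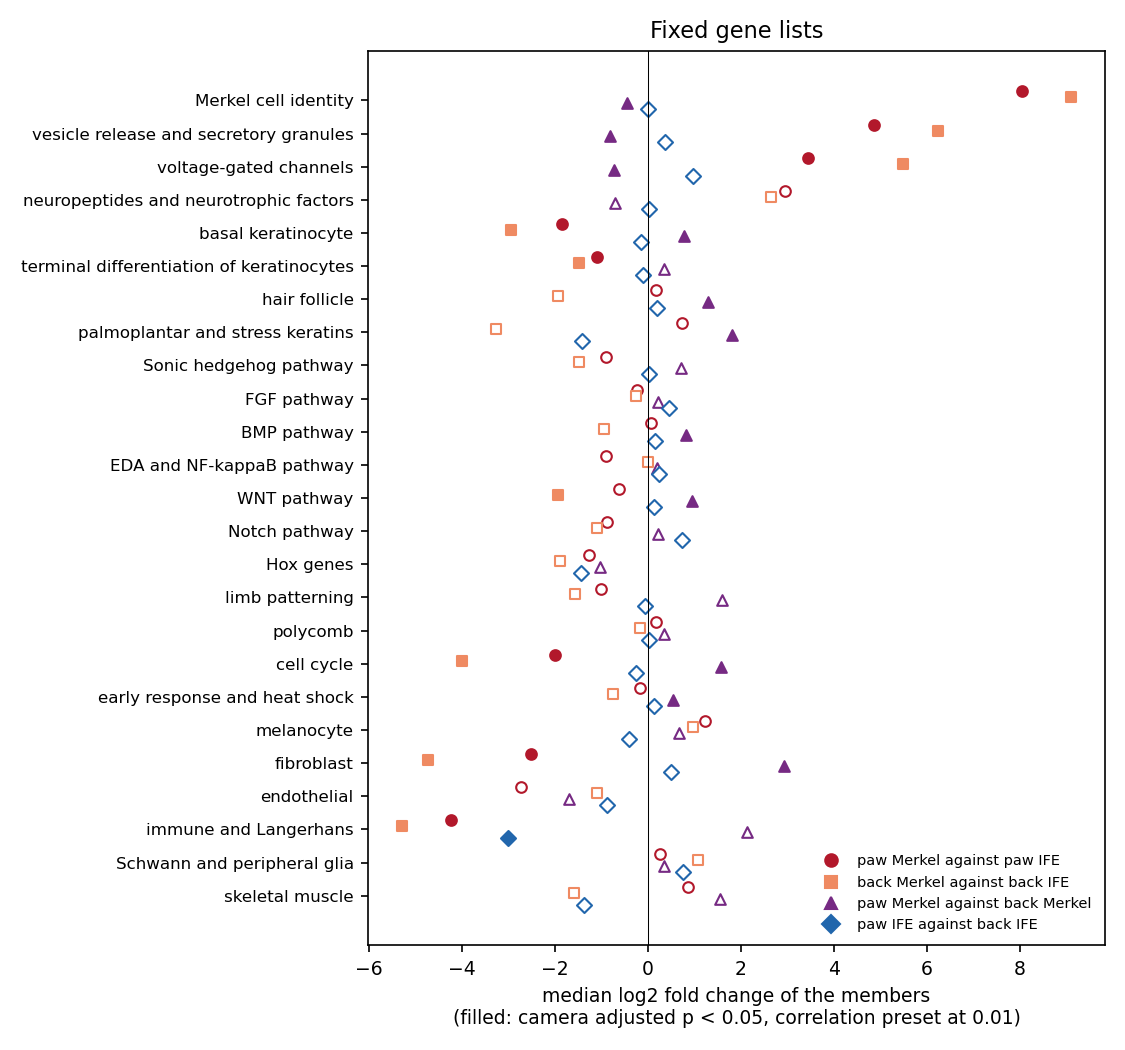
Median log2 fold change of the 25 tested gene lists (horizontal axis, genes at their bound) in the paw and back comparisons of Merkel with IFE cells and the paw and back comparisons within Merkel and IFE cells; each point is 1 list, filled where the camera adjusted p was under 0.05. Merkel identity genes stand at 8.03 in the paw and 9.10 in back skin, and cell cycle genes at -1.99 and -4.00.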

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

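The tests of IFE carry-over, of sequencing depth and of immune cells given here were chosen only after the results were seen, while the test of keratinocyte RNA in paw Merkel library 1 was set before its result was seen.

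For 8 gene lists the difference between Merkel and IFE cells was itself different between paw and back skin by camera on the interaction. Their adjusted p-values were 3.26e-11 for cell cycle genes, 8.6e-06 for immune markers, 0.00463 for vesicle release genes, 0.0154 for channels, 0.0339 for Merkel identity, basal keratinocyte and hair follicle genes, and 0.0391 for BMP genes. With an estimated correlation 0 of the 8 passed (adjusted p from 0.325 to 0.517), and by the edgeR test 0 single genes did, against 1365 at an unadjusted p under 0.05, 273 by DESeq2 and 0 by limma-trend. Cell cycle, immune, basal, hair follicle and BMP genes stood higher in the paw contrast, and vesicle, channel and identity genes lower. Without paw Merkel library 1 only cell cycle and immune genes among the 8 kept their call, and the other 6 ran from 0.225 to 0.531.

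A separate signal lay in the deposited FPKM values of genes without counts. Sap25, a subunit of a histone deacetylase complex, had a mean of 37.4 FPKM in Merkel cells and 0 counts in every library. Its FPKM was 29.6 ± 11.4 in paw Merkel against 14.6 ± 5.60 in paw IFE cells (log2 fold change 0.97, limma adjusted p = 0.326) and 45.2 ± 20.3 in back Merkel against 11.6 ± 7.56 in back IFE cells (log2 fold change 1.94, limma adjusted p = 0.0369). Sap25 shares 76.6% of its exonic bases with another annotated gene, Gm20605, and Lrch4 shares 77.2% of its own with the same gene. The signals of Sap25 and Lrch4 may thus not be separate. Sap25 is 1 of 39 genes with a mean of at least 1 FPKM over the libraries and no counts. It was the only one of them with a limma adjusted p under 0.05 in which each Merkel library exceeded each IFE library. In back skin alone, Snrpn (21.5 ± 9.25 against 0.752 ± 0.587 FPKM, log2 fold change 3.66, adjusted p = 0.0052) and Lrch4 (20.1 ± 0.694 against 5.24 ± 0.751 FPKM, log2 fold change 1.76, adjusted p = 0.045) were also higher in Merkel cells, and Pla2g4b, Prnd, Tgoln2, Rplp2-ps1 and Gm21992 were lower (adjusted p from 0.0197 to 0.0406). No explanation of these signals was tested.

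Cell cycle genes were higher in paw than in back Merkel cells, with a median log2 fold change of 1.57 over 36 genes (camera adjusted p = 3.55e-12, adjusted p = 0.288 with an estimated correlation). The median was still 1.565 after every library was thinned to the smallest total, where a depth effect was to bring it under 0.5. Thinning leaves the expected CPM ratios unchanged, so the median could hardly fall that far and this test does not decide on sequencing depth. IFE cells carried over into the paw Merkel sort remain open: the cell cycle genes would need a median of 25.95% IFE RNA in paw Merkel library 1 and 8.26% in library 2, and the basal keratinocyte genes 14.1% and 7.79%. The quartiles for the cell cycle genes, 18.4% to 30.0% and 0.584% to 25.1%, overlap those for the basal genes, 4.96% to 22.9% and 1.00% to 15.96%, so the test separates neither outcome. The gate for Merkel cells required GFP and excluded Sca1, which should remove IFE cells, and cycling paw Merkel cells stay an untested biological candidate explanation.

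Fewer genes passed the threshold between Merkel and IFE cells in the paw (941) than in back skin (2338). Depth alone is argued against, since after thinning the counts were 948 and 2368. Keratinocyte RNA in paw Merkel library 1 remains open. Genes called lower in back Merkel cells stood a median of 0.386 log2 higher in that library than in paw Merkel library 2 (quartiles -0.318 to 1.31). This met the bound of 0.5 set beforehand against this explanation. The explanation is left open because the upper quartile lay above 0.5, a criterion that was not set beforehand. Genes called higher in back Merkel cells had a median of -0.54, outside the range within 0.5 of 0 set for this explanation. Added keratinocyte RNA would itself lower the share of Merkel transcripts, so this value does not count against the explanation. Over all genes tested the median was 0.109 (quartiles -0.717 to 1.41). Terminal differentiation genes went with the explanation, at a summed 7300 CPM in paw Merkel library 1 against 1160 CPM in library 2. Basal keratinocyte genes differed less (8718 and 6948 CPM). Vesicle release genes (4331 and 8187 CPM), channels (759 and 2086 CPM) and identity genes (5977 and 7756 CPM) were lower in library 1 than in library 2. Neuropeptide genes went the other way (359 and 181 CPM). Of the genes called lower in back Merkel cells 63.2% were higher in paw Merkel library 1 than in library 2, against 29.4% of the genes called higher there and 53.0% of all genes tested. A true difference between the skin sites was tested only by the interaction. By the edgeR test it called 0 single genes (smallest adjusted p = 0.0600), though in simulated data it recovered only 5.97% of genes changed 4-fold. By camera 8 lists passed, and 0 with an estimated correlation. Whether the counts of 941 and 2338 reflect such a difference was not tested.

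The immune list was lower in paw than in back IFE cells (median log2 fold change -3.01, camera adjusted p = 1.34e-10, adjusted p = 0.848 with an estimated correlation). Immune cells in the back IFE sort are a candidate source that remains open: of 14 list members outside the class II genes and Cd74, 11 (78.6%) were lower in paw IFE cells, with a median of -2.60, short of the 80% set for this explanation and far from the bound against it. By the mean of back IFE libraries 1 and 2, which differed strongly, the most abundant markers were Cd74 (483 and 59.6 CPM), H2-Ab1 (304 and 42.4 CPM), H2-Aa (174.7 and 25.2 CPM) and Thy1 (35.8 and 117 CPM), and of these 4 all but Thy1 (91.8 and 85.0 CPM) were under 20 CPM in both paw IFE libraries. The gate on EpCAM should remove most white blood cells, though Langerhans cells, which live in the epidermis, carry EpCAM and the class II genes. No other list holds these genes, and a difference of the skin sites in resident immune cells was not tested.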

How the results depend on the processing

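The thinning of every library to the smallest total was chosen only after the data were seen, and the other alternatives were planned.

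With 2 libraries per group the number of genes past the threshold depends on the tool and on single libraries. Directions of named genes past it hardly changed, but these genes were chosen from the same data. Where their groups do not overlap, leaving out 1 library can hardly reverse a direction, so this is no independent support. The 183 results of named genes past the threshold had 3654 values under the alternatives: 3257 kept their direction and their side of the threshold, 396 kept the direction alone, and 1 reversed (Hoxc10 in back skin, 3.65 without back IFE library 2). No list past the threshold reversed (0), with 622 of its values on the same side and 147 past it no longer. Thinning to the smallest total gave 948, 2368, 20, 0 and 0 genes in the 5 comparisons, against 941, 2338, 28, 0 and 0. It shows only what fewer reads take away, so whether more depth would add calls was not tested. Scalings moved the median of all genes by at most 0.06. Where a value changed, the cause was not tested, unless it is said that fewer genes or a stricter threshold account for it.

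Comparisons are named in short as paw (Merkel against IFE), back (Merkel against IFE), Merkel sites (paw against back), IFE sites (paw against back) and interaction. Counts of genes past the threshold under DESeq2 were 2227 in paw, 3963 in back, 512 for Merkel sites, 84 for IFE sites and 273 for the interaction, with 1042 higher and 604 lower at both sites and 6 with the same site difference in both cell types, against 573, 241 and 0. RLE scaling gave 1 for the interaction. Without a filter on low counts there were 1920 in paw, 452 for Merkel sites, 120 for IFE sites and 305 for the interaction, 924 higher and 594 lower at both sites and 14 with the same site difference. At least 5 CPM in 2 libraries gave 15 for Merkel sites. Only the groups compared gave 537 in paw, 5 for Merkel sites, and 364 higher and 109 lower at both sites. The replicate block gave 1 for IFE sites and 4 for the interaction. The FPKM settings change the values, the test and the filter together. Limma on log2(FPKM + 1) gave 13 for Merkel sites, 2 for IFE sites and 2 for the interaction, and log2(FPKM + 0.1) gave 12 for Merkel sites and 1 for IFE sites. Limma on log2(FPKM + 1) without a filter gave 441 in paw, 8 for IFE sites, and 268 higher and 84 lower at both sites. An adjusted p under 0.01 gave 403 in paw, 1109 in back, 0 for Merkel sites, and 297 higher and 60 lower at both sites, which its stricter threshold accounts for. Upper-quartile scaling, the 2-fold minimum and limma-trend changed no count by more than 1.5 times, and where a count is not given for a setting it was within 1.5 times the reported one.

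Counts of gene lists past the threshold were 8 in paw, 9 in back, 11 for Merkel sites, 1 for IFE sites and 8 for the interaction. With an estimated inter-gene correlation they were 3, 3, 0, 0 and 0. The rank test on DESeq2 statistics gave 15 in back and 4 for IFE sites, and that on limma-trend statistics 3 for IFE sites. Without a filter on low counts there were 6 for Merkel sites and 4 for the interaction. At least 5 CPM gave 3 for IFE sites, the replicate block 7 for Merkel sites, log2(FPKM + 1) and log2(FPKM + 0.1) each 2 for IFE sites, and log2(FPKM + 1) without a filter 2 for IFE sites and 5 for the interaction.

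Reversals other than in leave-one-out fits were all of panel genes past no threshold, given as log2 fold changes. Under limma-trend they were Krt10 -0.0109, Shh -0.19 and Gli1 -0.43 for Merkel sites, and Krt18 0.67, Krt10 -0.47, Gli1 -0.41 and Ptch1 -0.0593 for the interaction. With the replicate block they were Sox2 -0.0337 and Gli1 0.62 for IFE sites, and Krt10 -0.16 and Gli1 -0.36 for the interaction. With log2(FPKM + 1), with and without a filter, they were Krt10 -0.11 and Shh -0.14 for Merkel sites, Krt18 -0.0005718 for IFE sites, and Krt8 0.11, Krt18 1.38, Krt10 -0.55 and Ptch1 -0.28 for the interaction. With log2(FPKM + 0.1) they were Krt10 -0.11 and Shh -0.33 for Merkel sites, Krt18 -0.27 for IFE sites, and Ly6a -0.21, Krt18 1.66, Krt10 -0.55 and Ptch1 -0.30 for the interaction. In the thinned libraries they were Sox2 -0.85 and Isl1 0.32 for IFE sites and Sox2 0.10 for the interaction.

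Leaving out each library in turn gave from 561 to 2369 genes in paw, 1307 to 3376 in back, 1 to 177 for Merkel sites, 0 to 67 for IFE sites and 0 to 41 for the interaction. Genes lower at both sites ran from 139 to 645, and genes with the same site difference from 0 to 9. Lists past the threshold ran from 2 to 10 for Merkel sites, 1 to 5 for IFE sites and 2 to 12 for the interaction. Log2 fold changes that crossed 0 in these fits ran as follows. In paw Edar ran from -4.06 to 0.078, and in back Ptch1 from -1.63 to 0.48 and Hoxc10 from -9.83 to 3.65. For Merkel sites Ly6a ran from -7.23 to 2.04, Krt10 from -2.22 to 1.94, Shh from -1.52 to 1.07 and Gli1 from -8.21 to 3.79. For IFE sites Sox2 ran from -0.75 to 0.63, Isl1 from -0.56 to 0.28, Krt8 from -0.28 to 3.72, Krt18 from -5.40 to 4.13, Krt10 from -0.11 to 0.96, Gli1 from -2.12 to 2.22 and Ptch1 from -2.04 to 0.0704. For the interaction Ly6a ran from -6.04 to 3.24, Sox2 from -1.38 to 0.004976, Krt8 from -2.79 to 1.20, Krt18 from -2.79 to 6.73, Krt10 from -2.76 to 1.41, Gli1 from -7.01 to 4.99, Ptch1 from -1.12 to 0.99, Edar from -2.21 to 1.94 and Bmp4 from -0.64 to 7.16.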

Other observations

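The tests of Hox and limb genes given here were chosen only after the values were seen.

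Miat, a long noncoding RNA of neurons chosen after its values were seen, was among the most abundant transcripts of Merkel cells. It measured 13810 ± 3594 CPM in paw Merkel against 15.3 ± 5.83 CPM in paw IFE cells (log2 fold change 9.82, SE 0.63, edgeR adjusted p = 6.18e-06) and 15190 ± 2699 against 15.5 CPM in back skin (log2 fold change 9.94, SE 0.64, adjusted p = 5.74e-06). It shares 30.4% of its exonic bases with other annotated genes.

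Malat1, a nuclear noncoding RNA, held 6.57% ± 2.49 of counts in paw Merkel, 6.82% ± 1.32 in back Merkel, 2.76% ± 0.292 in paw IFE and 3.07% ± 0.396 in back IFE cells, higher in each Merkel library than in each IFE library. Neat1 held 0.867% ± 0.731, 1.11% ± 0.102, 0.372% ± 0.021 and 0.108% ± 0.0533 in the same order, and in the paw its share in Merkel library 1 (0.35%) lay below both IFE libraries (0.387% and 0.357%).

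Each of the 8 libraries held both Xist (1689 to 7351 CPM) and transcripts of the Y chromosome, with Ddx3y from 44.1 to 103 CPM, Eif2s3y from 45.8 to 131 CPM, Kdm5d from 30.8 to 80.3 CPM and Uty from 18.1 to 95.4 CPM. The labels give no sex.

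Hox genes carry position along the body, so a hypothesis was that they mark the skin site alike in both cell types. Of 26 Hox genes above 1 CPM in some group, 17 (65.4%) had a paw minus back difference of the same sign in Merkel and IFE cells, between the bound of 80% set for the hypothesis and the bound of 50% set against it, so this remains open. The result turns on back IFE library 2: with back IFE library 1 alone the share was 76.9%, and with library 2 alone 34.6%. Hoxc10 measured 66.6 and 82.3 CPM in paw Merkel libraries 1 and 2 against 0.0761 and 0.0977 CPM in back Merkel libraries 1 and 2. In IFE cells it measured 62.3 and 73.4 CPM in paw libraries 1 and 2 against 0 and 83.9 CPM in back libraries 1 and 2. Hoxb3 measured 9.68 and 3.87 CPM in paw Merkel against 178.7 and 226 CPM in back Merkel libraries, and 6.44 and 2.47 CPM in paw IFE against 48.6 and 3.21 CPM in back IFE libraries. Over all genes the edgeR test called 0 Hox genes between paw and back in either cell type, and adjusted over the list alone it called 4 higher and 6 lower of 28 in Merkel cells and 0 in IFE cells.

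Back IFE library 2 may hold cells of the paw, through a wrong label or a mixed sample. Of 23 Hox and limb genes that differed at least 4-fold and without overlap between paw and back Merkel cells, it lay nearer to paw IFE library 1 than to back IFE library 1 in 19, and nearer to paw IFE library 2 in 19 (82.6%, where at least 80% was set for the hypothesis). Some of the 23 carry little weight: in the IFE libraries Sall4 was at 0.0543 CPM or less and Hoxa10 between 5.01 and 5.61 CPM. Tbx15, a limb gene, measured 61.3 CPM in back IFE library 2 against 37.3 and 15.1 CPM in paw IFE libraries 1 and 2 and 0.109 CPM in back IFE library 1, and En1 39.3 CPM against 24.7, 27.3 and 0 CPM. Immune markers set it apart from the paw IFE libraries only in part: of 14 list members outside the class II genes and Cd74 it lay above both paw IFE libraries in 9, within their range in 5 and below in 0. A simple swap is argued against by the paw IFE libraries, neither of which resembled back IFE library 1 in Hoxc10 or Hoxb3. Back skin taken from another place along the body remains open and was not tested. Without this library 67 genes differed between paw and back IFE cells, against 0 with it.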
